A study of Mus musculus with 12 samples.

How the data were processed

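RNA was measured by strand-specific messenger RNA sequencing (NuGEN kit) in 12 libraries of mouse embryonic fibroblasts, 3 for each combination of virus (RCAS-GFP, called vector, or RCAS-HOXB13) and day (1 or 21). Per the labels, cells were plated in triplicate wells, 1 plate was taken at day 1 and the other was kept in OsteoMAX-XF medium until day 21, so day, medium and plate go together. The deposited signal values are the authors' gene reads per 1000000 reads of the TMM-scaled (effective) library size (RPM), not log transformed. Every value above 0 in each library was a whole multiple of the value of 1 read within a tolerance of 0.01, and the sums of the values differed between libraries as the scaling factors did. The authors' notes name STAR 2.7.2a, HTSeq 0.6.1, edgeR and DESeq2 without saying which step made the values. They name the human build GRCh38, while the gene identifiers are mouse Ensembl identifiers. The mouse build that was used is not given in the sources used here.

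The table held 55573 genes, of which 55394 have an identifier in GENCODE M21 (GRCm38), the source of names, chromosomes and coordinates. No name was found for 250 genes, 229 shared a name with another gene and were kept apart by identifier, and 26173 had no read in any library. Recovered reads per library gave the depth, and 3 reads over a group of 3 libraries, the limit used for genes without reads, came to between 0.0614 and 0.0793 RPM. Intervals for ratios of reads are exact 95% intervals that cover counting error only, since reads from amplified libraries are not independent molecules. The ratio of effective to counted library size was 0.989 in vector and 1.15 in HOXB13 at day 1, and 1.01 and 0.956 at day 21. The 10 highest genes took 7.51% ± 0.23 and 4.95% ± 0.075 of reads in vector and HOXB13 at day 1, and 9.41% ± 0.32 and 8.12% ± 0.098 at day 21 (SD, n = 3).

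Genes with at least 1 RPM in at least 3 libraries were tested, 13516 in all, 454 of them on X and 6 on Y. Values were put on a log2 scale after adding 1. A model with 1 mean per group over all 12 libraries was fitted with limma 3.58.1 (eBayes with trend) in R 4.3.3. The 5 contrasts were HOXB13 against vector at day 1 and at day 21, day 21 against day 1 in vector and in HOXB13, and their interaction. Tests were two-sided, with p-values adjusted by Benjamini and Hochberg in each contrast and a threshold of 0.05. Adjusted p-values of genes are limma's unless edgeR or DESeq2 is named, and their ranges over the alternatives include both. Those of lists are from camera in limma with a preset correlation of 0.01 between genes, adjusted over 110 tests, with camera's estimated correlation beside it. The 22 gene lists were written from general knowledge. Only lists with at least 3 measured members were tested, and members below the filter were left out of the counts.

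Groups, contrasts, test, filter, pseudocount, lists, other settings to try and the rule for naming genes were fixed before the data were examined. The rule named, for each contrast, the 8 genes with the highest and the 8 with the lowest log2 fold change (5 and 5 for the interaction) among called genes with a mean of at least 5 in the higher group and no overlap between the groups' libraries (no such condition for the interaction). It left out predicted genes, mitochondrial genes and pseudogenes. It also named Hoxb13, Trp53, Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1, Col1a1, Sox9, Pparg, Acta2 and Mki67 in every contrast and up to 4 called members of each list with the largest log2 fold changes. Some genes that the rule names are not reported here. Other genes are single members of small counts, chosen after their values were seen. The 2-fold limit beside the test was added after seeing that most genes passed it.

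Alternatives were pseudocounts of 0.25 and 4, no filter and a filter of 5 RPM, rescaling by the median of ratios, quantile normalization, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a replicate block, only the libraries of each comparison, and leaving out each library in turn. RPM without the TMM factors and leaving out genes of chromosomes X and Y were added after the data were seen. Whether equal replicate numbers in different groups mark pairs was checked from residual correlations over 9433 genes: they ran from -0.0992 to 0.103 for equal numbers, with 1 of 18 above 0.1, so no pairing was used. Between vector and HOXB13 at day 1 they were 0.0318, 0.103 and 0.0392 for equal numbers, and -0.0742 to 0.0358 for unequal ones. Tests were also run on simulated data drawn with the spread of the real libraries, in which the levels of known genes had been changed. At day 1 limma found 46.8% of genes changed 1.2-fold, 89.6% of those changed 2-fold and 97.9% of those changed 4-fold, with 4.62% of its calls false. In the interaction it found 72.9% of genes changed 2-fold, with 6.63% of its calls false. Camera called a list raised in the simulation in all 5 contrasts, and of 21 other lists it called 1 at day 1, 1 at day 21 and 0 in the other contrasts. Simulated genes were drawn independently of each other and few were changed, while camera's estimated correlation in the real lists reached 0.553. The simulation therefore does not show how often camera with the preset correlation errs on lists whose genes move together. No library was left out.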

Results

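RNA was sequenced from mouse embryonic fibroblasts of mice that lack p53 and carry TVA, the receptor through which avian RCAS retroviruses enter mammalian cells. The cells had been given RCAS virus with GFP, called vector here, or RCAS virus with HOXB13, a homeobox transcription factor. RNA was taken from confluent cells at day 1 and from cells kept until day 21 in OsteoMAX-XF, a commercial medium that drives osteogenic differentiation. Each of the 4 groups had 3 libraries, 12 in all. By its title, the series asks what excess HOXB13 does to osteogenic differentiation. The wells were plated in triplicate and nothing in the labels says that they came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

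Gene reads per library ranged from 11109392 to 13594129 in vector and 13529964 to 14938139 in HOXB13 at day 1, and from 12173173 to 13235707 in vector and 13299600 to 15154317 in HOXB13 at day 21. Levels are given as gene reads per 1000000 reads of the authors' TMM-scaled library size (RPM), as mean ± SD (n = 3). Log2 fold changes, each with its standard error, and adjusted p-values come from limma unless another tool is named. Across genes, log2 levels of replicate libraries correlated with Pearson's r from 0.997 to 0.998, and those of libraries from different groups with r from 0.832 to 0.937. The first principal component held 56.6% of the variance and parted day 21 from day 1. The second held 31.3% and parted vector from HOXB13. Mitochondrial genes took 1.14% ± 0.065 of gene reads in vector and 1.38% ± 0.037 in HOXB13 at day 1, and 2.67% ± 0.16 in vector and 1.75% ± 0.042 in HOXB13 at day 21 (SD, n = 3). Between replicates most genes varied so little that small differences passed the test, so counts of genes that also changed at least 2-fold are given first.

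Reads at Hoxb13 matched the labels in every library. The gene (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447, plus strand, GRCm38, GENCODE M21) stood at 0.375 ± 0.197 RPM in vector and 327 ± 3.28 in HOXB13 at day 1. At day 21 it stood at 0.343 ± 0.197 in vector and 248 ± 8.59 in HOXB13. The log2 fold change between the viruses was 7.91 ± 0.10 at day 1 (adjusted p = 5.69e-26) and 7.54 ± 0.10 at day 21 (adjusted p = 5.75e-26). The vector level of Hoxb13 lay below the pseudocount of 1, and the log2 fold change was 6.24 with a pseudocount of 4 and 9.80 by edgeR at day 1, and 5.86 and 9.49 at day 21. Whether the virus carried human or mouse HOXB13 is not given in the sources used here, and a human sequence would be counted only where its reads matched the mouse gene. Trp53, the gene deleted in the donor mice (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), had reads in every group, at 53.4 ± 1.19 RPM in vector and 45 ± 0.33 in HOXB13 at day 1, and at 36.7 ± 2.05 and 32.1 ± 0.745 at day 21. Gene totals do not show which exons those reads came from, so they do not check the deletion.

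**Figure D1:**
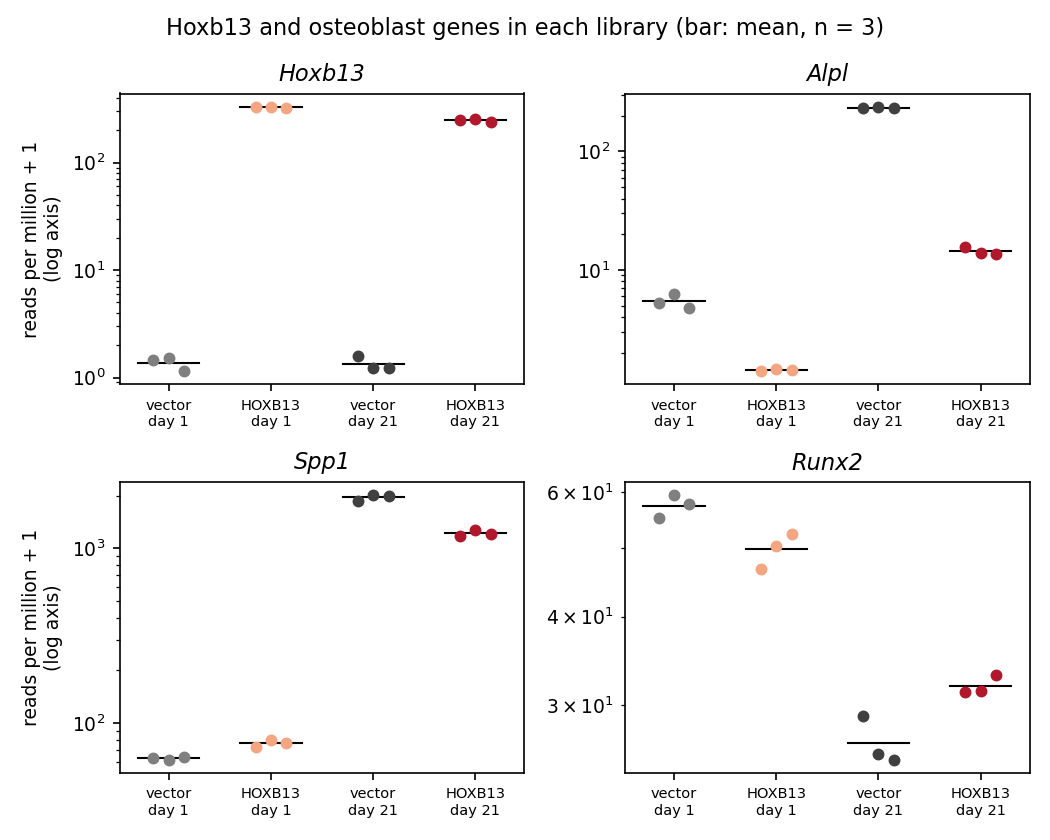
RPM plus 1 on a log axis in each library of the 4 groups, for Hoxb13, Alpl, Spp1 and Runx2; each point is 1 library and each bar the mean of 3. Alpl reached 232 RPM in vector and 13.4 in HOXB13 at day 21, and Spp1 1964 and 1224.

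The vector and HOXB13 libraries also differed in genes of the sex chromosomes. Xist, the noncoding RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254), stood at 427 ± 28.8 RPM in vector and 0.332 ± 0.162 in HOXB13 at day 1, and at 158 ± 8.03 and 0.303 ± 0.164 at day 21. The Y-linked genes went the other way. Ddx3y stood at 0.171 ± 0.183 in vector and 98.3 ± 1.32 in HOXB13 at day 1, and at 0.13 ± 0.0897 and 106 ± 2.09 at day 21. Eif2s3y had 3 reads over the 3 vector libraries of day 1 and 42.7 ± 0.478 RPM in HOXB13, a ratio of 538 with a 95% counting interval of 184 to 2610. Every one of the 12 libraries followed this division, so each comparison between the viruses below is also a comparison between libraries with Xist and libraries with Y-linked transcripts.

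**Figure D2:**
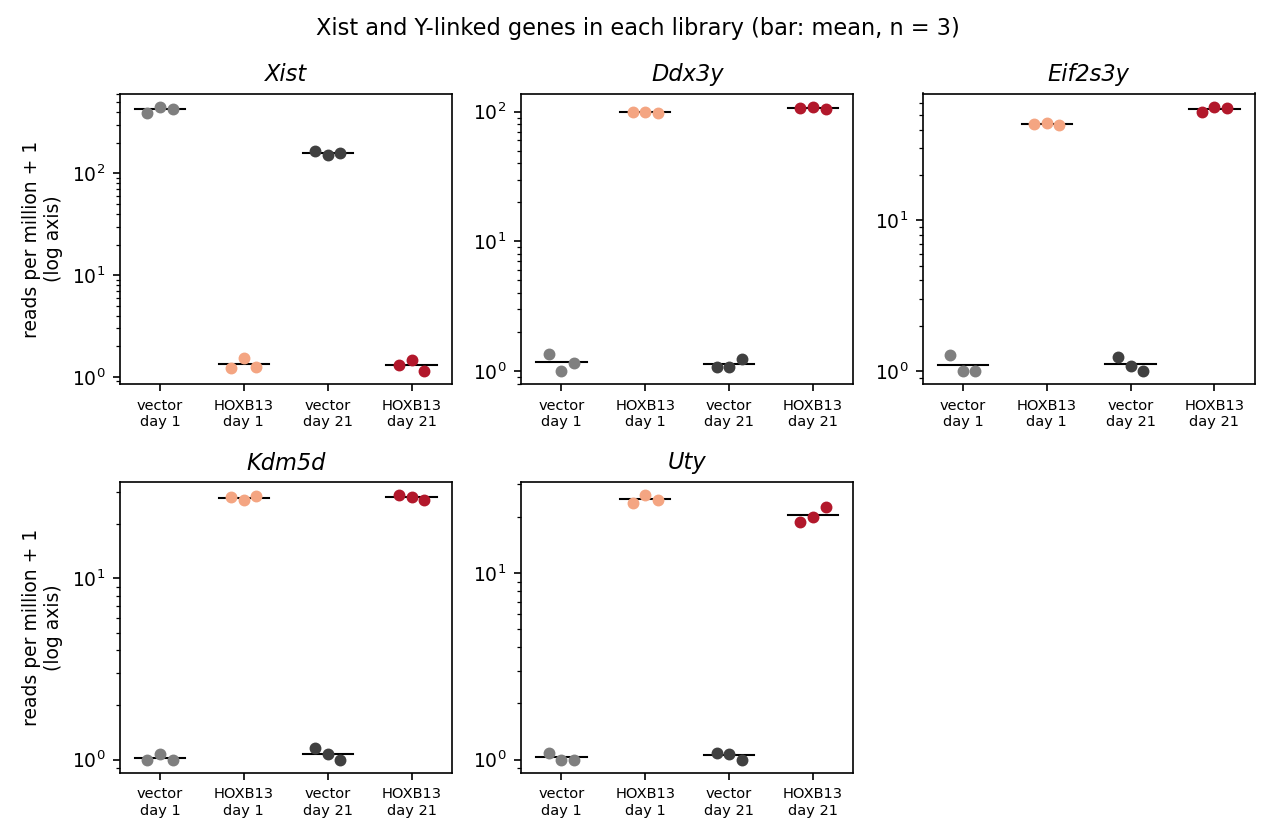
RPM plus 1 on a log axis in each library for Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty; each point is 1 library and each bar the mean of 3. Xist lies at 151 RPM or more in the 6 vector libraries and at 0.519 or less in the 6 HOXB13 libraries, and the 4 Y-linked genes show the opposite order.

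At day 1, before the osteogenic medium, HOXB13 cells differed from vector cells most evenly in 2 of the fixed gene lists. The other Hox genes, transcription factors of body-axis patterning, were lower: 24 of 26 measured members fell and 1 rose (median log2 fold change -2.19, camera adjusted p = 2.92e-07, adjusted p = 0.0275 with an estimated correlation). The size of that median rested on the pseudocount, with -1.24 for a pseudocount of 4, -2.83 for 0.25 and -3.41 by edgeR. Interferon-stimulated genes were higher, with 20 of 21 rising and 0 falling (median log2 fold change 2.32, camera adjusted p = 7.06e-09, adjusted p = 0.273 with an estimated correlation). Smooth muscle genes and matrix genes were mostly lower, by list tests that passed with the preset correlation and not with an estimated one. The question at this time point is how confluent HOXB13 and vector cells differed without differentiation medium, whether through HOXB13 or through the cultures themselves.

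Among Hox genes, Hoxc8 fell from 37.7 ± 1.45 RPM in vector to 1.72 ± 0.207 in HOXB13, with a log2 fold change of -3.83 ± 0.13. The log2 fold change of Hoxc5 was -3.35 ± 0.12, that of Hoxa3 -3.15 ± 0.12 and that of Hoxc9 -3.14 ± 0.15. By edgeR Hoxc5 came to -4.82 and Hoxc9 to -4.46, and with a pseudocount of 4 to -2.01 and -1.88. Hoxb6 was the member that rose, from 11.9 ± 1.79 to 17.1 ± 0.447. Among interferon-stimulated genes, Usp18, which removes ISG15 from proteins, rose from 1.25 ± 0.283 to 27.5 ± 3.08 with a log2 fold change of 3.66 ± 0.31. Ifit1, an inhibitor of viral RNA translation, rose from 4.95 ± 1.46 to 60.2 ± 8.26, and Irf7, a transcription factor of the interferon response, from 1.04 ± 0.324 to 19.2 ± 1.76. Rtp4 rose by 3.52 ± 0.24 on the log2 scale.

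Contractile genes went down in HOXB13 at day 1. Of the smooth muscle list, 12 of 14 members fell and 1, the myosin light chain kinase gene Mylk, rose (median log2 fold change -1.07, camera adjusted p = 6.5e-05, adjusted p = 0.266 with an estimated correlation). Acta2, smooth muscle actin, fell from 8577 ± 100 to 2882 ± 91.2, Tagln from 3851 ± 10.8 to 980.3 ± 27.5 and Myh11 from 57.6 ± 1.88 to 12.6 ± 0.746. In the matrix list 19 of 26 fell and 6 rose (median log2 fold change -0.56, camera adjusted p = 0.00151, adjusted p = 0.269 with an estimated correlation), with a median of -0.26 under quantile normalization. Postn, which encodes periostin, fell from 1286 ± 47.1 to 208 ± 13.1 and Timp3, a metalloproteinase inhibitor, from 1707 ± 37.1 to 535 ± 4.93. Under quantile normalization the matrix list was no longer called (adjusted p = 0.0745, range 4.12e-06 to 0.0745 over the alternatives with the preset correlation). Of the BMP and TGF-β targets, 9 of 16 fell and 4 rose (median log2 fold change -0.69, camera adjusted p = 0.0431, adjusted p = 0.192 with an estimated correlation). Ccn2, a matricellular growth factor gene, fell from 2414 ± 53 to 747 ± 14. Of the inflammatory genes 10 of 17 fell and 3 rose (median log2 fold change -0.63, camera adjusted p = 0.0376, adjusted p = 0.349 with an estimated correlation). The interleukin gene Il33 had a log2 fold change of -3.30 ± 0.10, the complement gene C3 of -3.24 ± 0.07 and the cytokine gene Lif of -3.13 ± 0.10. With only the 6 libraries of the comparison in the fit, neither the BMP and TGF-β list (adjusted p = 0.0618, range 0.00264 to 0.0618 over the alternatives) nor the inflammatory list (adjusted p = 0.0753, range 0.00229 to 0.0753) was called.

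Cell cycle genes were slightly lower in HOXB13 at day 1: 24 of 28 fell and 1, Ccnb2, rose (median log2 fold change -0.34, camera adjusted p = 9.06e-05, adjusted p = 0.297 with an estimated correlation). The median came to -0.22 under quantile normalization and -0.13 without the TMM factors. Mki67, a proliferation marker, stood at 563 ± 11.1 in vector and 455 ± 9.19 in HOXB13, a log2 fold change of -0.31 ± 0.04 that came to 0.01 under quantile normalization. Epithelial genes were lower by a larger margin, with 5 of 6 falling and 1, Krt19, rising (median log2 fold change -2.34, camera adjusted p = 0.0212, adjusted p = 0.192 with an estimated correlation). Krt14 fell from 25.2 ± 0.669 to 0.0798 ± 0.0692 and Krt8 from 81.6 ± 0.912 to 2.72 ± 0.164, and without a filter on low values the list was not called (adjusted p = 0.175, range 0.00152 to 0.175). All 8 measured mesothelial markers, chosen outside the fixed lists after this comparison had been seen, were lower in HOXB13 as well (median log2 fold change -1.74).

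Ranked with the pseudocount of 1, the genes with the largest differences at day 1 lay partly outside these lists. Besides Hoxb13 and the Y-linked genes, the steepest increases were those of Stmn2, a neuronal microtubule regulator, from 0.411 ± 0.209 to 171 ± 1.35, and Car3, a carbonic anhydrase, from 0.16 ± 0.0775 to 90.4 ± 4.3. Kcnj2, a potassium channel gene, rose from 1.24 ± 0.12 to 111 ± 1.25. Sfrp2, a secreted Wnt modulator, rose from 8.8 ± 0.396 to 399 ± 13.3 and Gpnmb from 1.06 ± 0.347 to 60.7 ± 1.63. Besides Xist, the steepest decreases were those of Sprr2k, a cornified envelope gene, from 95.1 ± 3.13 to 0.41 ± 0.0427, the uroplakin gene Upk1b from 429 ± 9.6 to 7.73 ± 0.422, Akap5 from 117 ± 2.71 to 2.23 ± 0.415, Scel from 60.3 ± 0.875 to 0.994 ± 0.245 and Podxl, which encodes podocalyxin, from 173 ± 9.51 to 4.83 ± 1.06. By edgeR the order differed, and Krt14, at -8.07, came before Sprr2k, at -7.78.

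Osteoblast genes did not move as a group at day 1. Alpl, the tissue-nonspecific alkaline phosphatase (ENSMUSG00000028766, chromosome 4, 137741733 to 137796384), was low in both groups, at 4.43 ± 0.775 in vector and 0.43 ± 0.0233 in HOXB13, with a log2 fold change of -1.92 ± 0.10 (adjusted p = 1.47e-14). The HOXB13 level of Alpl lay below the pseudocount of 1, and the log2 fold change was -0.92 with a pseudocount of 4, -2.77 with 0.25 and -3.30 by edgeR on the recovered reads. Col1a1, the main bone collagen gene, was lower in HOXB13, at 5761 ± 81.8 against 13604 ± 197. Spp1, osteopontin, was slightly higher, at 75.4 ± 3.48 against 61.8 ± 1.09. Runx2, the master transcription factor of osteoblasts, stood at 56.4 ± 2.1 in vector and 48.8 ± 2.83 in HOXB13, a log2 fold change of -0.20 ± 0.06 that vanished without the TMM factors (0.00). Of the osteoblast matrix list 6 of 14 rose and 7 fell (adjusted p = 0.802), and of the osteoblast transcription factors and inducers 6 of 14 rose and 6 fell (adjusted p = 0.802).

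In all, 1792 of 13516 tested genes passed limma's test at day 1 and changed at least 2-fold, 973 of them higher and 819 lower in HOXB13. Without the fold limit 9796 passed, 4586 higher and 5210 lower. Without the TMM factors, which differed between the groups, 9960 passed and the division was 6675 higher to 3285 lower, while the median log2 fold change of all genes moved from -0.03 to 0.15. With a pseudocount of 4 the genes at least 2-fold changed came to 1105, with 0.25 to 2306 and by edgeR to 2562. The lists not called were fatty acid and sterol synthesis (10 of 20 higher, 4 lower), adipocyte (6 of 11 higher, 4 lower), cartilage (2 of 9 higher, 3 lower), skeletal muscle (1 of 3 lower) and Wnt targets (4 of 15 higher, 8 lower). Also not called were glucocorticoid response (5 of 13 higher, 6 lower), TALE cofactors (4 of 10 higher, 5 lower), hypoxia and glycolysis (3 of 14 higher, 7 lower) and p53 targets (6 of 15 higher, 8 lower). The same held for macrophage (1 of 4 higher, 2 lower), endothelial (3 of 5 higher, 2 lower) and neural genes (4 of 6 higher, 1 lower). Adjusted p-values of these lists ran from 0.0622 to 0.894. Other settings called fatty acid and sterol synthesis (adjusted p = 0.00718 under quantile normalization, 0.0205 without the TMM factors, range over the alternatives 0.00718 to 0.343) and neural genes (0.00803 without a filter, 0.0464 with a pseudocount of 4, range 0.00803 to 0.196). The medians of the osteoblast matrix, cartilage, skeletal muscle, glucocorticoid, TALE and hypoxia lists changed sign under another scaling, and median, mean or test differed in sign for the osteoblast transcription factor, cartilage, glucocorticoid, TALE and endothelial lists.

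At day 21 in osteogenic medium, the mineralization enzyme gene Alpl was far lower in HOXB13 than in vector cells, at 13.4 ± 1.09 against 232 ± 3.61 RPM, a log2 fold change of -4.02 ± 0.10 (adjusted p = 6.08e-21). Alpl was already lower in HOXB13 at day 1, before this medium. By edgeR its log2 fold change was -3.30 at day 1 and -4.11 at day 21. Smpd3, a sphingomyelinase gene needed for bone mineralization in mice, stood at 2.2 ± 0.861 in HOXB13 and 569 ± 6.96 in vector. Smpd3 was lower in HOXB13 at day 1 as well. Matrix and remodelling genes were higher in HOXB13, while the other Hox genes and the epithelial genes were lower. These 3 list calls passed with the preset correlation and not with an estimated one (adjusted p = 0.187, 0.0501 and 0.0501). Of the 8 measured mesothelial markers 7 were lower and 1 higher (median log2 fold change -3.22). This comparison is the nearest to the title's question, the state of the cells after culture in differentiation medium. It cannot tell an effect of HOXB13 from a difference between the cultures, since virus and sex chromosome genes divided the libraries alike.

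The other bone genes did not all move with Alpl. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) was lower in HOXB13, at 1224 ± 51.5 against 1964 ± 79.6, and Col1a1 slightly lower, at 8530.3 ± 209 against 9541 ± 682. Runx2 (ENSMUSG00000039153, chromosome 17, 44495987 to 44814797) was slightly higher, at 30.9 ± 1.02 against 25.6 ± 2.09 (log2 fold change 0.27 ± 0.06, adjusted p = 0.000267). Enpp1, which makes the mineralization inhibitor pyrophosphate, was higher, at 212 ± 9.64 against 29.7 ± 2.73, and Col24a1 rose by a log2 fold change of 1.58 ± 0.08. The osteoblast matrix list thus split, 6 of 14 rising and 6 falling (adjusted p = 0.893). In the transcription factor and inducer list 9 of 14 rose and 4 fell (adjusted p = 0.271). Bmp4 was lower, at 11.2 ± 0.96 against 35.2 ± 1.9, and Twist2, a repressor of osteoblast differentiation, higher, at 87.6 ± 4.15 against 30.0 ± 1.22. Tnfsf11, the osteoclast-inducing cytokine RANKL, was higher, at 107 ± 5.28 against 47.4 ± 4.09. The late osteoblast genes Sp7, Bglap, Ibsp, Dmp1 and Mepe did not pass the filter of 1 RPM in 3 libraries. Sp7 stood at 0.157 ± 0.14 in vector and 0.0485 ± 0.042 in HOXB13 at day 21, and Bglap at 0.026 ± 0.045 and 0 ± 0, against a limit of 0.0780 and 0.0743 RPM that 3 reads over the group's libraries would give. Levels of Sp7 and Bglap stayed below the filter in both groups, and smaller changes in them were not tested. Ibsp, bone sialoprotein, had 2 reads over the vector libraries and 17 over the HOXB13 libraries of day 21 (0.0509 ± 0.044 and 0.424 ± 0.066 RPM), and was not tested.

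In the matrix and remodelling list 20 of 26 members rose in HOXB13 and 3 fell (median log2 fold change 0.81, camera adjusted p = 3.05e-05, adjusted p = 0.187 with an estimated correlation). Postn stood at 1948 ± 89.8 against 201 ± 30.6, Tnc, which encodes tenascin C, at 4335 ± 169 against 501 ± 84.1, and the collagenase gene Mmp13 at 1358 ± 39 against 266 ± 12.9. Mmp2 rose by a log2 fold change of 1.80 ± 0.03. The 3 members that fell were Timp2, Loxl3 and Lox. Genes of fatty acid and sterol synthesis were higher by smaller amounts, with 15 of 20 rising and 3 falling (median log2 fold change 0.54, camera adjusted p = 0.000776, adjusted p = 0.297 with an estimated correlation). Lss rose by a log2 fold change of 1.04 ± 0.04, Cyp51 by 0.98 ± 0.03 and Hmgcs1 by 0.82 ± 0.03.

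Of the other Hox genes, 22 of 26 were lower at day 21 and 3 higher (median log2 fold change -1.06, camera adjusted p = 0.000267, adjusted p = 0.0501 with an estimated correlation). The Hox median was -0.61 with a pseudocount of 4 and -1.82 by edgeR. Hoxc8 stood at 1.47 ± 0.572 in HOXB13 and 11.2 ± 0.561 in vector, and Hoxa3 at 1.68 ± 0.252 and 12.3 ± 1.31. The 3 higher members were Hoxb5, Hoxb6 and Hoxb7, neighbours in the cluster that also holds Hoxb13, and Hoxb7 stood at 8.1 ± 0.583 against 2.48 ± 0.392. All 6 measured epithelial genes were lower (median log2 fold change -4.50, camera adjusted p = 3.05e-05, adjusted p = 0.0501 with an estimated correlation), with a median of -2.74 for a pseudocount of 4, -5.92 for 0.25 and -6.57 by edgeR. Krt18 stood at 0.372 ± 0.201 against 43.6 ± 1.84 and Cdh1, E-cadherin, at 0.604 ± 0.255 against 48.5 ± 0.956. Krt14 had 2 reads over the HOXB13 libraries, a ratio of 368 between vector and HOXB13 with a 95% counting interval of 101 to 3040. Cell cycle genes were lower by small amounts, 24 of 28 falling and 0 rising (median log2 fold change -0.35, camera adjusted p = 3.05e-05, adjusted p = 0.273 with an estimated correlation). Mki67 stood at 116 ± 6.93 against 158 ± 7.23.

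Ranked with the pseudocount of 1, the steepest increases at day 21 besides Hoxb13 and the Y-linked genes were those of Thbs4, a matricellular thrombospondin, from 0.443 ± 0.0503 in vector to 295 ± 19.4 in HOXB13, and Insyn2a, from 0.264 ± 0.131 to 97 ± 5.44. The cell adhesion gene L1cam rose from 0.129 ± 0.0413 to 52.8 ± 1.02, the chemokine gene Ccl8 from 0.832 ± 0.114 to 81.9 ± 0.485 and Serpina3h, which has near-identical paralogs that can share reads, from 1.77 ± 0.457 to 213 ± 3.33. Ranked the same way, the steepest decreases besides Xist and Smpd3 were those of Pkhd1l1, from 401 ± 15.2 to 1.39 ± 0.669, the uroplakin genes Upk1b, from 1216 ± 43 to 7.86 ± 1.28, and Upk3b, from 1155 ± 22.1 to 8.54 ± 1.09, Gpm6a, from 339 ± 14.3 to 1.49 ± 0.105, Muc16, from 174 ± 11.9 to 0.559 ± 0.339, and Podxl, from 189 ± 5.72 to 0.788 ± 0.105. Upk1b, Upk3b, Muc16, Krt8 and Krt18 are known from mesothelial and other epithelial cells. Among the genes named in every comparison, Sox9, a cartilage transcription factor, stood at 7.96 ± 1.36 against 19.3 ± 0.871, Pparg, an adipocyte transcription factor, at 0.722 ± 0.12 against 6.06 ± 0.55, and Acta2 at 267 ± 14.3 against 863 ± 14.4.

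In all, 2237 of 13516 genes passed limma's test at day 21 and changed at least 2-fold, 1102 higher and 1135 lower. Without the fold limit 9782 passed, 5037 higher and 4745 lower. Leaving out genes of chromosomes X and Y, 2148 genes passed at the 2-fold limit. Lists that were not called were interferon-stimulated (3 of 21 higher, 13 lower), smooth muscle (4 of 14 higher, 8 lower), BMP and TGF-β targets (5 of 16 higher, 11 lower) and glucocorticoid response (4 of 13 higher, 8 lower). Hypoxia genes (9 of 14 higher, 3 lower), neural genes (4 of 6 higher, 0 lower), TALE cofactors (3 of 10 higher, 7 lower) and Wnt targets (6 of 15 higher, 7 lower) were not called either. The same was true of cartilage (4 of 9 higher, 1 lower), skeletal muscle (2 of 3 lower), adipocyte (5 of 11 higher, 5 lower) and inflammatory genes (7 of 17 higher, 6 lower), of p53 targets (7 of 15 higher, 8 lower), and of macrophage (1 of 4 higher, 1 lower) and endothelial genes (3 of 5 higher, 1 lower). Their adjusted p-values ran from 0.111 to 0.99. Without a filter, interferon-stimulated genes (adjusted p = 0.0215, range over the alternatives 0.0192 to 0.357) and BMP and TGF-β targets (adjusted p = 0.0341, range 0.0341 to 0.195) were called. The medians of the inflammatory and macrophage lists changed sign under another scaling, and median, mean or test differed in sign for the adipocyte, inflammatory, TALE, p53, macrophage and endothelial lists.

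In vector cells, acute-phase and inflammatory genes, glucocorticoid-responsive genes and most measured bone matrix genes rose over 21 days with the osteogenic medium. Cell cycle, contractile and Hox genes fell. These list calls passed with the preset correlation and not with an estimated one, with adjusted p-values of 0.0501 to 0.205. Saa3, serum amyloid A, rose from 10.4 ± 1.16 to 5882 ± 364 RPM, Lcn2, lipocalin 2, from 3.21 ± 0.532 to 2253 ± 82.1, and C3 from 105 ± 3.61 to 14588 ± 700. Alpl rose from 4.43 ± 0.775 to 232 ± 3.61 with a log2 fold change of 5.44 ± 0.10, and Spp1 from 61.8 ± 1.09 to 1964 ± 79.6 with 4.97 ± 0.04. The rise of Alpl was 4.81 with a pseudocount of 4 and 5.72 by edgeR. Day and medium changed together, so this comparison measures both at once.

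Inflammatory genes rose in vector, 12 of 17 against 2 that fell (median log2 fold change 2.60, camera adjusted p = 0.000776, adjusted p = 0.192 with an estimated correlation). Cxcl5, a neutrophil chemokine, rose from 2.08 ± 0.125 to 457 ± 49.4 and Cxcl1 by a log2 fold change of 5.69 ± 0.10. Of the glucocorticoid-responsive genes 11 of 13 rose and 2 fell (median log2 fold change 2.75, camera adjusted p = 0.000107, adjusted p = 0.0501 with an estimated correlation). Zbtb16 rose from 0.215 ± 0.0618 to 60.7 ± 0.157, Pdk4, a kinase that restrains pyruvate oxidation, from 4.01 ± 0.622 to 204 ± 7.43, and Mt2, a metallothionein, from 7.16 ± 0.912 to 277 ± 2.68. Interferon-stimulated genes rose, 17 of 21 with 0 falling (median log2 fold change 1.08, camera adjusted p = 0.0103, adjusted p = 0.64 with an estimated correlation), and Bst2 went from 22.5 ± 3.15 to 129.9 ± 11.9.

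In the osteoblast matrix list 10 of 14 measured members rose in vector and 3 fell (median log2 fold change 0.60, camera adjusted p = 0.0395, adjusted p = 0.192 with an estimated correlation). Bglap, Bglap2, Ibsp, Dmp1, Mepe, Sost and Ifitm5 lay below the filter, with at most 7 reads each over the vector libraries of day 21. Pdpn, podoplanin, rose from 104 ± 4.07 to 451 ± 2.29 and Smpd3 from 168 ± 7.21 to 569 ± 6.96. The list was not called under quantile normalization (adjusted p = 0.0758, range over the alternatives 0.0115 to 0.0758). Runx2 fell from 56.4 ± 2.1 to 25.6 ± 2.09 and Col1a1 from 13604 ± 197 to 9541 ± 682. Osteoblast transcription factors and inducers mostly fell, 8 of 14 with 2 rising, without passing the list test (adjusted p = 0.212). Adipocyte genes rose, 8 of 11 with 1, Pparg, falling (median log2 fold change 1.04, camera adjusted p = 0.022, adjusted p = 0.198 with an estimated correlation). The fall of Pparg, -0.28 ± 0.11, was no longer called without replicate 1 (-0.22) or 3 (-0.27) of vector at day 1, nor without replicate 3 of vector at day 21 (-0.21). It was not called with a pseudocount of 0.25 (adjusted p = 0.0592), without a filter (0.0858) or by DESeq2 (0.143) either, with a range of 0.000142 to 0.143 over the alternatives. Lipe, hormone-sensitive lipase, rose from 3.46 ± 0.601 to 32.2 ± 0.509 and Dgat2, which makes triglyceride, from 6.16 ± 1.08 to 48.7 ± 1.84. The adipocyte list missed the threshold under quantile normalization (adjusted p = 0.0505, range 0.0148 to 0.0505).

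Every one of the 28 cell cycle genes fell in vector (median log2 fold change -1.75, camera adjusted p = 2.47e-12, adjusted p = 0.142 with an estimated correlation). Mki67 fell from 563 ± 11.1 to 158 ± 7.23 and Kif11, a spindle motor, had a log2 fold change of -2.27 ± 0.05. Of the smooth muscle genes 13 of 14 fell and 1, Mylk, rose (median log2 fold change -2.96, camera adjusted p = 1.05e-05, adjusted p = 0.205 with an estimated correlation). Acta2 fell from 8577 ± 100 to 863 ± 14.4, Actg2 from 209 ± 7.61 to 5.81 ± 2.13 and Cnn1, calponin, from 482 ± 2.31 to 15.6 ± 1.73. The other Hox genes fell, 24 of 26 with 0 rising (median log2 fold change -1.21, camera adjusted p = 0.000267, adjusted p = 0.0501 with an estimated correlation), and Hoxc5 went from 14.1 ± 1.9 to 1.22 ± 0.0232. Of the BMP and TGF-β targets 12 of 16 fell and 3 rose (median log2 fold change -0.75, camera adjusted p = 0.0156, adjusted p = 0.151 with an estimated correlation). Ccn2 had a log2 fold change of -2.24 ± 0.03.

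The remaining top genes of vector cells were Hp, haptoglobin, which rose from 2.9 ± 0.586 to 1632 ± 30.7, Lbp, from 2.57 ± 0.456 to 760.1 ± 17.2, Steap4, from 1.7 ± 0.33 to 565 ± 17.5, and Vnn1, from 1.09 ± 0.187 to 292 ± 4.85. Ranked with the pseudocount of 1, the steepest falls were those of Sprr2k, from 95.1 ± 3.13 to 0.26 ± 0.159, Cspg4, a pericyte proteoglycan, from 108 ± 4.17 to 1.61 ± 0.0487, Mcam, from 119 ± 2.38 to 2.05 ± 0.272, Tll1, from 70.8 ± 3.5 to 0.89 ± 0.218, Dlk1, from 156 ± 0.543 to 3.72 ± 1.25, and Lrrc15, from 122 ± 2.04 to 3.34 ± 0.38. By ratios of reads the order differed: Acta1 fell from 552 reads to 2, a ratio of 280 with a 95% counting interval of 77.3 to 2320, and Acan from 135 to 1. Of the 8 measured mesothelial markers, 6 rose with day in vector and 1 fell. Msln rose from 59.6 ± 5.35 to 668 ± 12.3, Cldn15 from 13.1 ± 2.1 to 111 ± 6.41 and Wt1 from 107 ± 4.4 to 261 ± 5.33. In HOXB13 4 of them rose and 2 fell, and Msln went from 23.6 ± 0.933 to 19.3 ± 5.43. In all, 3799 genes passed limma's test and changed at least 2-fold, 2173 higher and 1626 lower at day 21. Without the fold limit 11294 of 13516 passed, 5630 higher and 5664 lower. Lists that were not called were cartilage (2 of 9 higher, 5 lower), fatty acid and sterol synthesis (12 of 20 higher, 4 lower), skeletal muscle (1 of 3 higher, 2 lower), Wnt targets (6 of 15 higher, 6 lower) and matrix remodelling (9 of 26 higher, 16 lower). TALE cofactors (4 of 10 higher, 5 lower), hypoxia genes (6 of 14 higher, 7 lower), p53 targets (7 of 15 higher, 7 lower) and macrophage genes (2 of 4 higher, 0 lower) were not called either. Nor were endothelial (3 of 5 higher, 2 lower), epithelial (2 of 6 higher, 3 lower) and neural genes (1 of 6 higher, 4 lower). Fatty acid and sterol synthesis was called without a filter (adjusted p = 0.0145) and under quantile normalization (adjusted p = 0.0234), with a range of 0.0145 to 0.107 over the alternatives. The adjusted p-values of these lists ran from 0.0896 to 0.901, and median, mean or test differed in sign for the matrix remodelling, p53 and epithelial lists.

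HOXB13 cells over the same 21 days shared the rise of acute-phase genes and the fall of cell cycle and contractile genes, but their interferon-stimulated genes fell and their matrix remodelling genes rose. None of these 5 list calls passed with an estimated correlation, with adjusted p-values of 0.114 to 0.448. Saa3 rose from 7.45 ± 0.0677 to 12401 ± 579 and Lcn2 from 2.96 ± 0.236 to 4544 ± 63.7. Alpl rose from 0.43 ± 0.0233 to 13.4 ± 1.09, a log2 fold change of 3.33 ± 0.10 (adjusted p = 1.41e-19) that was 1.97 with a pseudocount of 4 and 4.91 by edgeR, and Spp1 from 75.4 ± 3.48 to 1224 ± 51.5. Of the interferon-stimulated genes 20 of 21 fell and 0 rose (median log2 fold change -2.0, camera adjusted p = 9.7e-05, adjusted p = 0.448 with an estimated correlation). Of the matrix list 22 of 26 rose and 3 fell (median log2 fold change 1.19, camera adjusted p = 1.65e-06, adjusted p = 0.142 with an estimated correlation), with a median of 0.60 under quantile normalization.

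Ifit1 fell from 60.2 ± 8.26 to 4.87 ± 0.829 in HOXB13, Usp18 from 27.5 ± 3.08 to 2.87 ± 0.534 and the chemokine gene Cxcl10 from 14 ± 1.96 to 1.09 ± 0.309. Mmp13 rose from 1.29 ± 0.108 to 1358 ± 39, Mmp3, stromelysin, from 12.4 ± 2.09 to 1354 ± 75.1, Mmp2 from 172 ± 4.53 to 2115 ± 39.9 and Postn from 208 ± 13.1 to 1948 ± 89.8. Inflammatory genes rose, 13 of 17 against 3 (median log2 fold change 2.81, camera adjusted p = 9.06e-05, adjusted p = 0.151 with an estimated correlation), with Nos2 going from 0.107 ± 0.136 to 108 ± 10.3. Glucocorticoid-responsive genes rose, 10 of 13 against 3 (median log2 fold change 1.97, camera adjusted p = 0.000267, adjusted p = 0.0501 with an estimated correlation). Hsd11b1, which regenerates active glucocorticoid, had 1 read over the HOXB13 libraries of day 1 and 91.5 ± 8.65 RPM at day 21, a ratio of 4490 with a 95% counting interval of 805 to 177000. Mt2 rose from 13.4 ± 0.729 to 922 ± 6.22 and Zbtb16 from 0.536 ± 0.254 to 42.3 ± 2.26.

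Fatty acid and sterol genes rose, 16 of 20 with 2 falling (median log2 fold change 0.71, camera adjusted p = 0.000267, adjusted p = 0.273 with an estimated correlation), among them Insig1 by a log2 fold change of 1.47 ± 0.04 and Lss by 1.32 ± 0.04. Of the adipocyte list 9 of 11 rose and 1, Pparg, fell (median log2 fold change 0.81, camera adjusted p = 0.0156, adjusted p = 0.192 with an estimated correlation). Lpl, lipoprotein lipase, rose from 17.3 ± 1.42 to 505 ± 5.28 and Fabp4 from 55.6 ± 3.85 to 362 ± 3.79, while Pparg fell from 5.43 ± 0.327 to 0.722 ± 0.12. Of the osteoblast matrix list 10 of 14 rose and 4 fell (median log2 fold change 1.25, camera adjusted p = 0.0165, adjusted p = 0.151 with an estimated correlation). Pdpn rose from 98.1 ± 3.88 to 808 ± 7.93 and Col24a1 from 12 ± 0.808 to 82.9 ± 5.8. Under quantile normalization that list was not called (adjusted p = 0.102, range 0.00148 to 0.102). Col1a1 rose from 5761 ± 81.8 to 8530.3 ± 209, a log2 fold change of 0.57 ± 0.04 that turned to -0.58 under quantile normalization.

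All 28 cell cycle genes fell in HOXB13 (median log2 fold change -1.82, camera adjusted p = 8.49e-14, adjusted p = 0.114 with an estimated correlation), Mki67 from 455 ± 9.19 to 116 ± 6.93. Of the smooth muscle list 11 of 14 fell and 1, Mylk, rose (median log2 fold change -2.15, camera adjusted p = 8.28e-05, adjusted p = 0.269 with an estimated correlation), with Cnn1 going from 449.7 ± 18.1 to 11.9 ± 2.77 and Acta2 from 2882 ± 91.2 to 267 ± 14.3. Of the neural genes 5 of 6 fell (median log2 fold change -1.62, camera adjusted p = 0.0283, adjusted p = 0.273 with an estimated correlation). Gap43 fell from 83.2 ± 3.2 to 0.941 ± 0.107, Map2 from 213 ± 2.95 to 5.49 ± 0.774 and Stmn2 from 171 ± 1.35 to 40.3 ± 4.12. That call ended with a filter of 5 RPM (adjusted p = 0.067) and without the TMM factors (adjusted p = 0.0902), with a range of 0.004 to 0.0902 over the alternatives. Other steep changes were the rises of Hp, from 1.79 ± 0.497 to 3141 ± 85.4, Steap4, from 0.914 ± 0.23 to 1657 ± 54.8, Lgi2, from 0.961 ± 0.0351 to 1049 ± 5.62, and Chil1, from 0.249 ± 0.115 to 427 ± 6.78. Among the steepest falls were those of Dlk1, from 212 ± 9.44 to 1.29 ± 0.0667, Rab3b, from 108 ± 3.09 to 0.294 ± 0.19, Ptn, pleiotrophin, from 386 ± 23.9 to 4.99 ± 1.55, Car3, from 90.4 ± 4.3 to 0.967 ± 0.479, Nptx1, from 47.5 ± 4.61 to 0.0977 ± 0.036, and Kctd12, from 199 ± 4.48 to 4.14 ± 0.577.

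In HOXB13 cells 3196 genes passed limma's test between the days and changed at least 2-fold, 1778 higher and 1418 lower at day 21. Without the fold limit 10830 passed, 5341 higher and 5489 lower. Without the TMM factors 11207 passed, 3865 higher and 7342 lower, and the median log2 fold change of all genes moved from -0.01 to -0.24. Lists that were not called were osteoblast transcription factors and inducers (5 of 14 higher, 8 lower), cartilage (3 of 9 higher, 5 lower), skeletal muscle (1 of 3 lower), BMP and TGF-β targets (4 of 16 higher, 11 lower) and Wnt targets (4 of 15 higher, 7 lower). Hox genes (3 of 26 higher, 10 lower), TALE cofactors (3 of 10 higher, 6 lower), hypoxia genes (8 of 14 higher, 5 lower) and p53 targets (8 of 15 higher, 4 lower) were also not called. Macrophage (3 of 4 higher, 1 lower), endothelial (1 of 5 higher, 3 lower) and epithelial genes (1 of 6 higher, 4 lower) were not called either. BMP and TGF-β targets (adjusted p = 0.00725, range over the alternatives 0.00725 to 0.158) and p53 targets (adjusted p = 0.0448, range 0.0448 to 0.276) were called without a filter. The adjusted p-values of these lists ran from 0.0578 to 0.893, and median, mean or test differed in sign for the osteoblast transcription factor list.

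**Figure D3:**
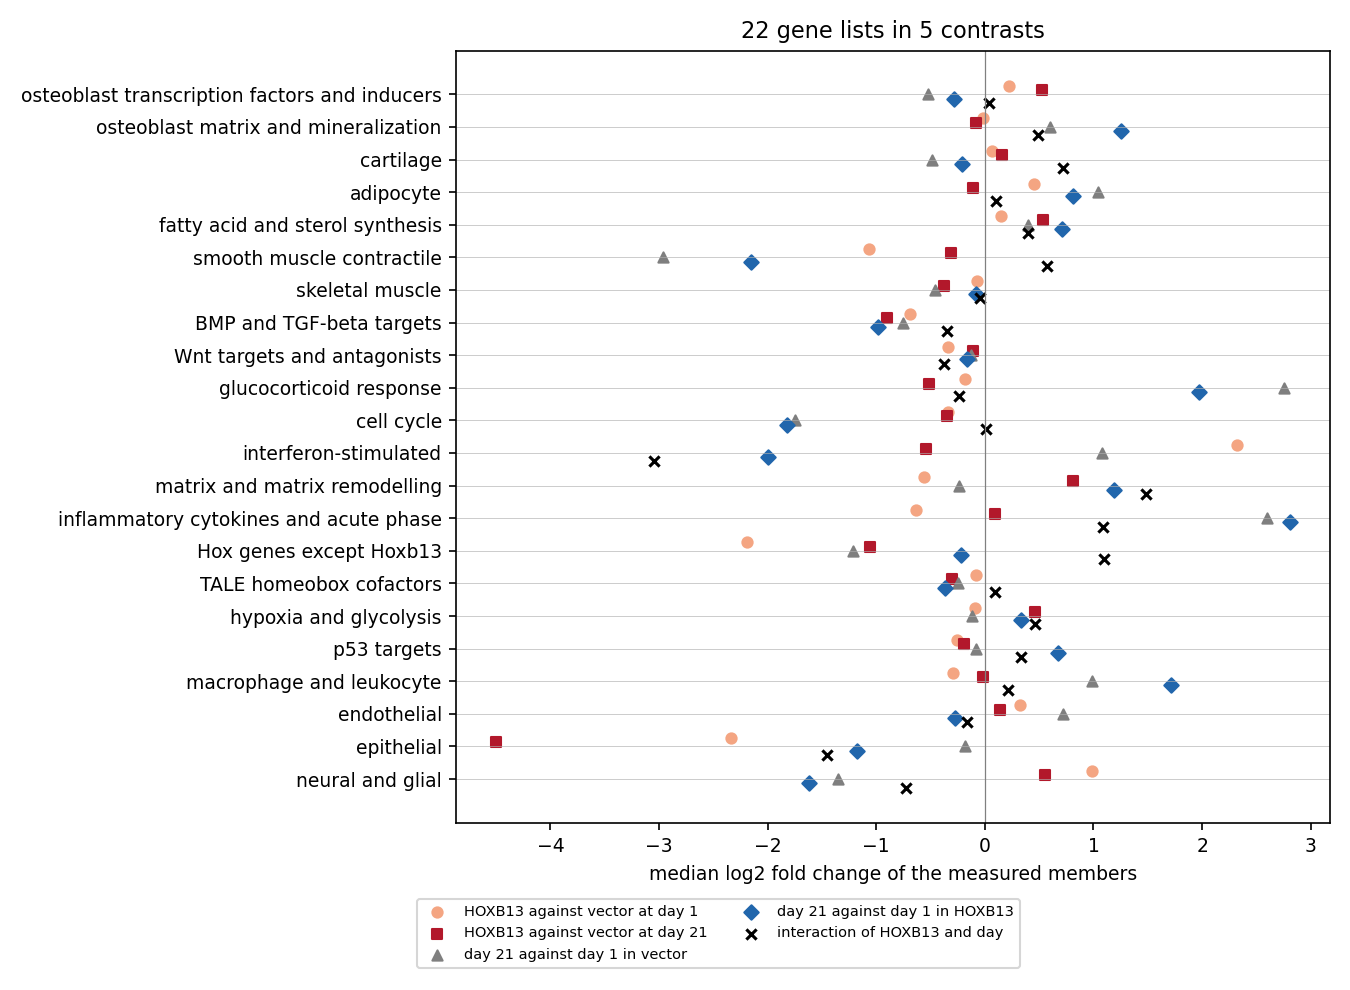
Median log2 fold change of the measured members of each of 22 gene lists in the 5 contrasts, 1 symbol per contrast. Interferon-stimulated genes lie at 2.32 for HOXB13 against vector at day 1 and at -0.54 at day 21, and matrix genes at -0.56 and 0.81.

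The interaction of virus and day asks whether the difference between HOXB13 and vector changed between the days. Matrix genes gained in HOXB13 relative to vector and interferon-stimulated genes lost, by list tests that did not pass with an estimated correlation (adjusted p = 0.0831 and 0.273). Postn was lower in HOXB13 at day 1 and higher at day 21, an interaction of 5.91 ± 0.09 on the log2 scale. Alpl had an interaction of -2.11 ± 0.14 (adjusted p = 2.47e-12), a size that rested on the pseudocount. It was -2.84 with a pseudocount of 4, -1.33 with 0.25, -0.81 by edgeR (adjusted p = 0.049) and -0.76 by DESeq2 (adjusted p = 0.0476), with a range of adjusted p-values of 1.08e-17 to 0.049 over the alternatives. In Pparg, at 0.722 ± 0.12 RPM in HOXB13 at day 21, the interaction was -1.63 ± 0.16, with -0.80 for a pseudocount of 4 and -2.62 by edgeR.

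Of the matrix list 22 of 26 members had a positive interaction that passed and 3 a negative one (median interaction 1.48, camera adjusted p = 7.06e-09, adjusted p = 0.0831 with an estimated correlation). Tnc had an interaction of 3.57 ± 0.09, Eln, elastin, of 3.14 ± 0.18 and Mmp13 of 2.92 ± 0.09. All 21 interferon-stimulated genes had a negative interaction that passed (median interaction -3.05, camera adjusted p = 4.58e-09, adjusted p = 0.273 with an estimated correlation). Irf7 had an interaction of -4.40 ± 0.30 (-2.88 with a pseudocount of 4, -5.72 by edgeR), Cxcl10 of -4.36 ± 0.24 and Oasl2 of -4.35 ± 0.20. Of the other Hox genes 22 of 26 had a positive interaction and 1, Hoxb3, a negative one (median interaction 1.10, camera adjusted p = 0.00154, adjusted p = 0.0672 with an estimated correlation), which followed the fall of Hox genes in vector between the days. By edgeR 18 Hox genes had a positive interaction that passed. Of the fatty acid and sterol genes 14 of 20 were positive and 3 negative (median interaction 0.40, camera adjusted p = 0.014, adjusted p = 0.413 with an estimated correlation), and of the hypoxia and glycolysis genes 9 of 14 and 1 (median interaction 0.46, camera adjusted p = 0.023, adjusted p = 0.214 with an estimated correlation). Hk2, hexokinase 2, had an interaction of 1.77 ± 0.06 and Cyp51 of 1.03 ± 0.04. Neither list was called under quantile normalization, with adjusted p = 0.202 (range over the alternatives 8.01e-05 to 0.202) and adjusted p = 0.0758 (range 0.00264 to 0.0758). Of the epithelial genes 5 of 6 were negative and 1, Krt14, positive (median interaction -1.45, camera adjusted p = 0.0212, adjusted p = 0.192 with an estimated correlation). The interaction of Krt14, which had few reads in HOXB13 at both days, rested on the pseudocount, at 0.41 with 1 and -0.20 by edgeR, where no epithelial gene had a positive one that passed. The epithelial call ended with a pseudocount of 4 (adjusted p = 0.149) and without the TMM factors (adjusted p = 0.102), with a range of 0.0108 to 0.149.

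**Figure D4:**
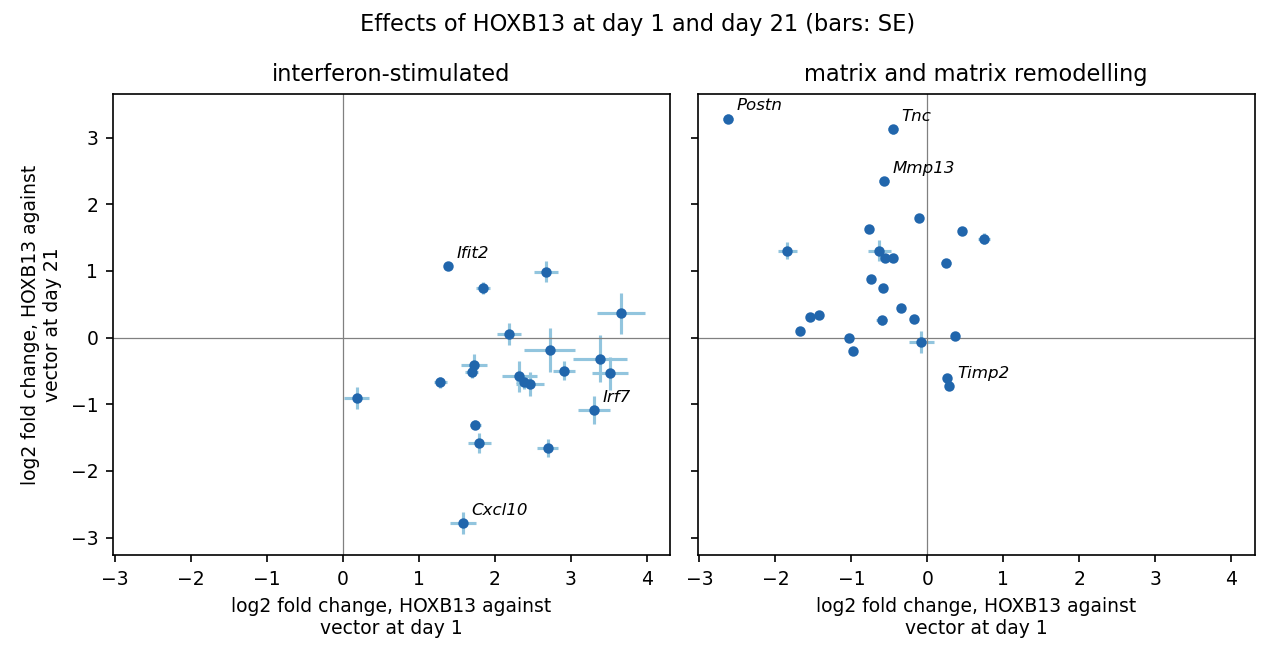
Log2 fold change of HOXB13 against vector at day 1 (horizontal axis) and at day 21 (vertical axis) for the measured genes of the interferon-stimulated and matrix lists; each point is 1 gene and bars are standard errors. Interferon-stimulated genes spread to the right of 0 at day 1, and Postn lies at -2.63 at day 1 and 3.28 at day 21.

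The largest positive interactions were those of Crispld2, at 6.56 ± 0.04, Thbs4, at 5.91 ± 0.14, Postn, Sprr2k, at 5.83 ± 0.17, and Ccl8, at 5.53 ± 0.16. Ccl8 had 3 reads in each group of day 1 and Sprr2k 2 reads in HOXB13 at day 21, and the sizes of most of these interactions rested on the pseudocount. With a pseudocount of 4 and by edgeR they came to 4.16 and 6.91 for Ccl8 and 5.19 and 6.45 for Thbs4, against 6.41 and 6.58 for Crispld2 and 5.87 and 5.88 for Postn, so by edgeR Ccl8 came before Crispld2. Sprr2k came to 4.42 with a pseudocount of 4, 6.42 with 0.25 and 5.45 by DESeq2. Crispld2 stood at 258 ± 2.69 in vector and 29.4 ± 1.23 in HOXB13 at day 1, and at 145 ± 5.12 and 1610.1 ± 26.7 at day 21. Among the largest negative ones were those of the flavin monooxygenase gene Fmo2, at -6.48 ± 0.17, Kcnj2, at -5.91 ± 0.14, Car3, at -5.62 ± 0.20, and Spock2, at -5.56 ± 0.16. With a pseudocount of 4 and by edgeR these came to -4.93 and -7.88 for Fmo2, -4.64 and -6.83 for Kcnj2, -4.27 and -6.94 for Car3 and -4.50 and -6.40 for Spock2. Fmo2 rose from 0.246 ± 0.152 to 134 ± 4.21 in vector, while HOXB13 had 0.184 ± 0.01 at day 1 and 0.45 ± 0.151 at day 21. Runx2 had an interaction of 0.47 ± 0.08, Spp1 of -0.96 ± 0.05, Sox9 of -1.34 ± 0.13 and Pparg of -1.63 ± 0.16. Col1a1 had an interaction of 1.08 ± 0.05 that came to -0.03 under quantile normalization. Trp53 did not pass, at 0.06 ± 0.07 (adjusted p = 0.48), but was called in the other direction without the TMM factors (-0.23, adjusted p = 0.00487, range over the alternatives 0.00487 to 0.903).

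By limma's test 2352 genes had an interaction of at least 1 on the log2 scale, 1064 positive and 1288 negative. Without that limit 9220 of 13516 passed, 4941 positive and 4279 negative. Without the TMM factors 9662 passed, 2821 positive and 6841 negative, with the median of all genes moving from 0.03 to -0.23. With a pseudocount of 4 the genes past the limit of 1 came to 1561, with 0.25 to 2802 and by edgeR to 2658. The uncalled lists were osteoblast transcription factors and inducers (6 of 14 positive, 4 negative), osteoblast matrix (8 of 14 positive, 5 negative), cartilage (5 of 9 positive, 2 negative), adipocyte (4 of 11 positive, 3 negative) and smooth muscle (9 of 14 positive, 3 negative). Skeletal muscle (1 of 3 negative), BMP and TGF-β targets (7 of 16 positive, 8 negative), Wnt targets (6 of 15 positive, 7 negative), glucocorticoid response (4 of 13 positive, 7 negative) and cell cycle genes (11 of 28 positive, 8 negative) were also not called. The same held for inflammatory genes (9 of 17 positive, 4 negative), TALE cofactors (5 of 10 positive, 4 negative), p53 targets (9 of 15 positive, 4 negative), and macrophage (1 of 4 positive, 1 negative), endothelial (1 of 5 positive, 2 negative) and neural genes (1 of 6 positive, 4 negative). Their adjusted p-values ran from 0.0649 to 0.905. Inflammatory genes were called without the TMM factors (adjusted p = 0.00277), without a filter (0.00725), with a filter of 5 RPM (0.04) and under quantile normalization (0.0421), with a range of 0.00277 to 0.0853 over the alternatives. Smooth muscle genes were called without a filter (adjusted p = 0.0101) and without the TMM factors (0.0325), with a range of 0.0101 to 0.497. The medians of the osteoblast transcription factor, adipocyte, cell cycle and TALE lists changed sign under another scaling, and median, mean or test differed in sign for the osteoblast matrix, BMP and TGF-β, TALE and cell cycle lists.

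Of the genes changed at least 2-fold, 388 were higher in HOXB13 at both days where 79.3 would be shared by independent lists, and 399 were lower at both days where 68.8 would be. Another 80 went in opposite directions, against 149 for independent lists. Hoxb13, Gpnmb and the Y-linked genes were among those higher at both days, and Upk1b, Podxl and Smpd3 among those lower. The comparisons shared no library. Both set HOXB13 against vector cultures that also differed in sex chromosome genes, so a lasting difference between the cultures would recur at both days. The overlap therefore cannot tell an effect of HOXB13 from such a difference. Between vector and HOXB13, the change from day 1 to day 21 was shared by more genes of longer lists, with 1056 genes higher in both, against 286 for independent lists, 779 lower in both, against 171, and 89 opposite, against 442. Across the 13516 genes the log2 fold changes of the viruses at day 1 and day 21 correlated with Pearson's r of 0.49 and Spearman's rho of 0.40, and the changes with day in vector and HOXB13 with 0.68 and 0.68. Genes are not independent replicates, so no p-value is given for these.

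Across the 22 lists and 5 comparisons, 38 of 110 list tests were called with the preset correlation of 0.01. With an estimated correlation only that of the Hox genes at day 1 was called (adjusted p = 0.0275). The median of 13 of the 38 called lists moved over 1.5 times with a pseudocount of 0.25 or 4, by edgeR or by DESeq2, and that of 0 changed sign. Besides those given above, the medians with a pseudocount of 4 and by edgeR were -0.40 and -0.70 for inflammatory genes at day 1, 2.19 and 4.34 for inflammatory genes and 0.83 and 1.45 for osteoblast matrix with day in HOXB13, and -1.21 and -2.59 for neural genes there. With day in vector they were 0.47 and 1.27 for osteoblast matrix, 0.50 and 1.25 for adipocyte genes, 0.72 and 1.38 for interferon-stimulated genes and -0.72 and -1.61 for Hox genes. In the interaction they were 0.70 and 1.07 for Hox genes and -0.59 and -2.45 for epithelial genes. Under another scaling 7 of the 38 medians moved over 1.5 times and 0 changed sign. Besides those given above, matrix genes came to 0.94 in the interaction under quantile normalization, and without the TMM factors fatty acid and sterol genes came to 0.47 with day in HOXB13 and 0.13 in the interaction, and hypoxia and glycolysis genes to 0.21 in the interaction. The counts of changed members adjusted over the list alone equalled those above in 102 of the 110 tests and differed by 1 or 2 genes in the other 8. Adjusted over the list alone, 14 interferon-stimulated genes were lower at day 21 instead of 13, and 8 Hox genes fell with day in HOXB13 instead of 10. Setting members with 3 or fewer reads in a group at 3 reads moved the median of no list by more than 0.036 in the comparisons of 2 groups.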

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

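Of the tests here, those for swapped libraries, for cultures of different sex chromosomes or origin, for genes of X and Y, for mesothelial markers and for leukocytes were chosen after the results were seen. What brought the following results up for a closer look is that the difference between HOXB13 and vector changed between day 1 and day 21, by limma's interaction test. Groups of 3 libraries are too small to test for a single deviating library. Read counts of replicates differed most in pairs with replicate 2 at day 1. Their chi-square per degree of freedom, over genes with at least 20 reads, was 4.49 and 5.82 in vector and 3.97 and 2.54 in HOXB13. For replicates 1 and 3 of day 1 it was 1.36 in vector and 1.71 in HOXB13.

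The interaction passed for 9220 of 13516 genes. On the log2 scale it was 6.56 for Crispld2, 5.91 for Thbs4, 5.91 for Postn, 5.83 for Sprr2k and 5.53 for Ccl8, and -6.48 for Fmo2, -5.91 for Kcnj2, -5.62 for Car3 and -5.56 for Spock2. Among the genes named in every comparison it was -2.11 for Alpl (-0.81 by edgeR, adjusted p = 0.049, and -0.76 by DESeq2, adjusted p = 0.0476, range over the alternatives 1.08e-17 to 0.049), -1.63 for Pparg (-2.62 by edgeR), -1.34 for Sox9, -0.96 for Spp1, 0.47 for Runx2 and 1.08 for Col1a1, which came to -0.03 and lost its call under quantile normalization (adjusted p = 0.504, range over the alternatives 2.81e-97 to 0.504). Smaller ones were -0.37 for Hoxb13, -0.14 for Mki67 and -0.12 for Acta2, and each of these calls ended without 1 or more single libraries and without a filter on low values. That of Hoxb13 also ended with a pseudocount of 0.25 (-0.33, adjusted p = 0.278), by edgeR (-0.31, adjusted p = 0.648) and by DESeq2 (-0.28, adjusted p = 0.686), with a range of 6.34e-05 to 0.686 over the alternatives. The sizes of the interactions of Ccl8, Sprr2k, Thbs4, Fmo2, Kcnj2, Car3, Spock2, Alpl and Pparg rested on the pseudocount. Among lists, adjusted p-values with the preset correlation were 4.58e-09 for interferon-stimulated genes, 7.06e-09 for matrix genes, 0.00154 for Hox genes, 0.014 for fatty acid and sterol synthesis, 0.0212 for epithelial genes and 0.023 for hypoxia and glycolysis. None of these 6 list calls held with an estimated correlation, the lowest adjusted p-values being 0.0672 for Hox genes and 0.0831 for matrix genes.

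The virus labels were also exchanged within each day. Of 100 such labelings, the real one included, 2 gave as many genes as the real 9220. The other was the highest, 10538, which points to a structure of the samples: a labeling that exchanges the viruses at 1 day only keeps every group together and adds up the effects of virus at the days instead of subtracting them. Labelings that mix the viruses put the difference between them into the spread within groups, with or without an interaction. The exchange therefore does not decide whether chance or an interaction gave the count. For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split was the 1 with the most calls in each, with 9796 at day 1, 9782 at day 21, 11294 with day in vector and 10830 with day in HOXB13, and the highest other split gave 0.

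The sex chromosome genes divided the libraries by virus. The Y-linked sum of Ddx3y, Eif2s3y, Kdm5d and Uty was 0.0742 to 0.727 RPM in the vector libraries and 190 to 210.2 in the HOXB13 libraries, and Xist in HOXB13 was 0.109% of its level in vector. That 0 of 12 libraries lay on the other group's side restates this division, so it is no separate test of a swap between libraries. Levels of Hoxb13 argue against a swap between the viruses, at 0.571 RPM or less in vector libraries and 238 or more in HOXB13 libraries. An exchange between days within 1 virus would not show in the sex chromosome genes. The values are consistent with cultures of different sex chromosomes: genes that escape X inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, had a median log2 fold change of -0.64 at day 1, and of -0.58 at day 21. These values argue against loss of the Y chromosome alone, or of Xist expression alone, as what parts the cultures. Each side had transcripts that the other lacked, Xist at 151 RPM or more in vector libraries and a Y-linked sum of at least 190 in HOXB13 libraries. Neither loss was tested further.

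The broad difference between the viruses, Hox genes included, may come from HOXB13 or from the cultures themselves. Genes of X and Y alone do not make up this difference, since 96% of the genes changed at least 2-fold at day 21 lay on neither. With 454 genes on X and 6 on Y among 13516 tested, that share had to be high, so it is a count and not a test. The scalings tried do not account for the lower Hox genes, with a median at day 1 of at most -2.06. They moved the median of all genes at day 1 only between -0.028 and 0.154, too little to undo the Hox median. Mesothelial-type cells or identity in the vector culture remain open: of 10 markers, listed after lower Upk1b, Upk3b, Muc16 and keratin genes had prompted this explanation but before their own values were looked at, 8 were measured, with a median log2 fold change of -3.22 at day 21 and 7 of them lower in HOXB13, the exception being Aldh1a2 at 0.39, and with day in vector 6 rose and 1 fell (median 1.52), while 8 were already lower in HOXB13 at day 1 (median -1.74). Msln stood at 668 RPM in vector and 19.3 in HOXB13 at day 21 and Wt1 at 261 and 14.8, none of the markers is in another list, and fibroblasts of embryos may express some of them. A different origin of the cultures cannot be told apart from HOXB13 as a source, since 0 libraries of either virus carried the sex chromosome genes of the other.

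The interferon-stimulated genes were higher in HOXB13 at day 1 (camera adjusted p = 7.06e-09, 0.273 with an estimated correlation), while at day 21 13 of 21 were lower and the list was not called (0.117 and 0.758). The scalings tried do not account for this change between the days, with a median interaction of the list of at most -2.97. They moved the median interaction of all genes only between -0.232 and 0.029, too little to undo that of the list. Leukocytes in the HOXB13 culture are argued against: the sum of Ptprc, Tyrobp, Laptm5, Fcer1g, Lyz2, C1qa, C1qb and C1qc reached at most 0.26 RPM in a HOXB13 library at day 1. What stays open is a response to HOXB13, to the virus stock or to a culture of different origin, none of which the design can part.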

How the results depend on the processing

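RPM without the TMM factors, the version without genes of X and Y and the 2-fold limit were chosen after the data were seen. Of 261 comparisons of a count with its alternatives, 258 stayed within 1.5 times the reported count. The genes changed ranged from 8736 to 10175 at day 1, 8639 to 10772 at day 21, 9919 to 12626 with day in vector, 9558 to 11828 with day in HOXB13 and 7841 to 9662 for the interaction. Leaving out single libraries gave 9311 to 9434, 9435 to 9490, 11037 to 11098, 10467 to 10555 and 8861 to 9012, in the same order. At the 2-fold limit the other settings gave 1105 to 2562, 1496 to 2820, 2601 to 4610, 2253 to 3929 and 1561 to 2802. The 3 exceptions were counts at the 2-fold limit with a pseudocount of 4, which shrinks changes of low genes, at 1105 genes at day 1 (1792 reported) and 1561 for the interaction (2352 reported), and the list tests with an estimated correlation, of which 1 was called instead of 38. The estimated correlation lay below the preset 0.01 for Hox genes (0.001), osteoblast matrix (0.003), BMP and TGF-β targets (0.005) and glucocorticoid response (-0.022). A higher correlation within these lists therefore does not account for the calls they lost. It lay above the preset for other lists, up to 0.553 for interferon-stimulated genes. What else raised the adjusted p-values was not tested. Other settings called 35 to 45 list tests, and leaving out single libraries 38 to 41. The filter of 5 RPM left 95 list tests.

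With the replicate block, limma called 9763 genes at day 1, 9750 at day 21, 11289 with day in vector, 10810 with day in HOXB13 and 9182 for the interaction. Of the reported calls it kept 9728 of 9796, 9700 of 9782, 11248 of 11294, 10773 of 10830 and 9128 of 9220.

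Of 9565 comparisons of named genes, 9461 kept direction and call, 95 lost the call, 4 gained it and 5 reversed. Sizes could move while direction and call were kept: the interaction of Alpl was -2.11 with the pseudocount of 1, -1.33 with 0.25, -2.84 with 4, -0.81 by edgeR and -0.76 by DESeq2. The HOXB13 level of Alpl at day 1 lay below the pseudocount. Without the TMM factors Runx2 at day 1 came to 0.004 and the interaction of Trp53 to -0.225. Under quantile normalization Mki67 at day 1 came to 0.013, Col1a1 with day in HOXB13 to -0.582 and the interaction of Col1a1 to -0.025. The cause of these reversals was not tested. Trp53 (-0.03) and Pparg (-0.23) at day 1 lost their calls without the TMM factors. Sox9 at day 1 was called without the TMM factors (0.36), by edgeR (0.20) and without replicate 1 of HOXB13 at day 1 (0.25). Of the interactions, those of Hoxb13, Acta2 and Mki67 ended without a filter on low values. That of Hoxb13 also ended with a pseudocount of 0.25 (-0.33), by edgeR (-0.31) and by DESeq2 (-0.28), and without replicate 1 of HOXB13 (-0.36) or 3 of vector (-0.24) at day 1, or without replicate 3 of HOXB13 (-0.34) or 1 of vector (-0.25) at day 21. That of Acta2 ended without replicate 1 of HOXB13 (-0.09) or 3 of vector (-0.11) at day 1, or 3 of HOXB13 at day 21 (-0.07). That of Mki67 ended without replicate 1 (-0.13) or 2 (-0.13) of HOXB13 or 1 of vector (-0.13) at day 1, or 2 of HOXB13 (-0.10) or 3 of vector (-0.10) at day 21.

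Of 1987 comparisons of list tests, 1913 kept direction and call, 50 lost the call (37 with an estimated correlation), 24 gained it and 0 reversed. Those gained under other settings stand in the report with their ranges. No list call was lost by leaving out a library. List calls gained by it were neural genes at day 1 without replicate 2 of HOXB13 (0.0476) or 1 of vector (0.0443), interferon-stimulated genes at day 21 without replicate 3 of vector (0.0192), and BMP and TGF-β targets with day in HOXB13 without replicate 2 of day 1 (0.0476) or of day 21 (0.0381). For the interaction they were inflammatory genes without replicate 3 of HOXB13 at day 1 (0.0408), and smooth muscle genes without replicate 3 of HOXB13 (0.0432) or of vector (0.0385) at day 21. Depth limits small changes of genes below 1 RPM, such as Sp7 and Bglap.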

Other observations

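The genes below were chosen after their values were seen, and no explanation was tested for them. Levels are means in RPM ± SD (n = 3).

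Among single complement genes, C1s1 stood at 13.3 ± 1.03 in vector and 4.16 ± 0.366 in HOXB13 at day 1, and at 399.8 ± 19.1 and 256 ± 2.14 at day 21. C4b rose from 0.505 ± 0.119 to 90.4 ± 9.66 in vector and from 0.245 ± 0.0547 to 95.6 ± 5.62 in HOXB13. Serping1, the inhibitor of the first complement protease, rose from 2.43 ± 0.559 to 193 ± 18.6 in vector and from 3.79 ± 0.608 to 887 ± 12.8 in HOXB13. The protease inhibitor gene Serpina3n, which shares sequence with neighbouring genes of its family, rose from 3.07 ± 0.777 to 422 ± 25.9 in vector and from 9.23 ± 1.24 to 3122 ± 50.9 in HOXB13.

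B2m, the light chain gene of MHC class I, stood at 176 ± 6.71 in vector and 382 ± 14.6 in HOXB13 at day 1, and at 281 ± 27.7 and 1185 ± 24.6 at day 21. The heavy chain gene H2-D1 stood at 65.7 ± 3.33 and 142 ± 6.6 at day 1 and at 251 ± 25.3 and 1009.6 ± 15.8 at day 21, and H2-K1 at 44.3 ± 0.839 and 62.7 ± 0.827 and at 216 ± 7.95 and 502 ± 2.89. The lysosomal protease gene Ctsk, known from osteoclasts and fibroblasts, stood at 73.6 ± 2.09 in vector and 792 ± 28.4 in HOXB13 at day 21, with a log2 fold change of 3.41 ± 0.04, and Ctsb at 812 ± 16.7 and 2086 ± 23.4.

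The ferritin gene Fth1 rose from 545 ± 3.81 to 17923 ± 338 in vector and from 545 ± 9.87 to 12858 ± 217 in HOXB13. Aldh1a1, a retinal dehydrogenase gene, stood at 4143 ± 46.6 in vector and 154 ± 3.25 in HOXB13 at day 21.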
